A study of Triticum aestivum with 10 samples.

How the data were processed

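The samples were whole wheat seedlings without the starchy endosperm, from 5 lines with 2 arrays each, and total RNA was labelled with biotin for a 1-colour Affymetrix wheat array. The deposited intensity values are the authors' signals on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. On each of the 10 arrays the mean after trimming 2% of values from each end was between 500.2 and 500.3, and medians were between 88.2 and 108.7. The deposited table held 61290 probe sets with signals from 0.0712 to 52602, and detection calls were not used here. The number of arrays limits the precision: the median half-width of the 95% interval of a log2 difference between 2 lines was 0.67.

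Signals were analysed as log2(signal + 16.9), where 16.9 is the 20th percentile of all values, so a fold change is on that scale and understates changes of dim probe sets. No further normalization was applied. The 111 AFFX control probe sets were left out, and so were 64 RPTR reporter probe sets, which the written design had not named. Probe sets with a mean log2 value above the 40th percentile were kept, a mean of 6.10, which left 36669. One model with the 5 lines as groups was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), and two-sided p-values were adjusted by the Benjamini-Hochberg method at 0.05. The fit had 5 residual degrees of freedom and 9.14 with the prior. Nothing in the labels says that the 2 samples of a line came from separate plants, so p-values measure only the spread between these samples, which may be technical.

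Probe sets lower than Pavon in both Dt1BL and 1RS.1BL were taken as wheat 1BS candidates, where 1BS is the short arm of chromosome 1B. In each recombinant line a candidate was called wheat-like when it lay above the mean of Dt1BL and 1RS.1BL and was not called different from Pavon, arm-lacking in the opposite case, and intermediate when it differed from both, with adjustment over the candidates alone. Rye 1RS candidates had to be higher in 1RS.1BL than in both Pavon and Dt1BL. In a further model 4 arrays with a wheat segment were set against the 6 without it.

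A platform table gave 1 gene symbol for 1273 of the 61290 probe sets and none for 60017, and 1272 of the symbols matched a gene ID in the IWGSC CS RefSeq v2.1 gene table. Chromosomes and gene order come from that table, whose assembly may differ from the source of the array's sequences, and no coordinates are given. Genes were named by a rule written before the data were examined: the called probe sets of largest change with no overlap between the arrays of the lines compared and with 1 gene symbol. Chance gives such a separation in 33.3% of probe sets with 2 arrays against 2. Few called probe sets had a symbol, so values of some probe sets without a gene name are also given, and these were chosen after their values were seen. The groups and comparisons, the alternatives and 15 gene lists were also fixed before the data were examined. Histones, tubulins and actins, and peroxidases and glutathione transferases had at least 5 probe sets tested, and storage proteins and photosystem proteins are described as markers of seedling makeup. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry.

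The procedure was tested on simulated data for Dt1BL against Pavon on 36669 probe sets, with 50 changed at each size. The changed probe sets were drawn from bright ones only, well above the filter. The simulated noise was independent between arrays, so the rates below do not cover dim probe sets or arrays that deviate together. It called 18% of those lowered by 1 log2 unit, 92% at 2 units, 96% at 3 units and 100% at 4 units, with 10 false calls among the unchanged. Of the simulated candidates, 83.3% at 1 unit and 95.6% at 2 units were placed in their segment class and the rest in no named class, and none in a wrong one. Alternatives were quantile normalization, pseudocounts at the 5th (3.46) and 40th (57.4) percentile, no filter, no trend, a replicate block, fits to only the 4 arrays compared, and leaving out each array. Added after the data were examined were a term for array median, a replicate block in 3 lines and array weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.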

Results

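Transcript signals were measured in seedlings of 5 wheat lines that differ in the short arm of chromosome 1B. Pavon is a complete wheat. Dt1BL is a ditelosomic line that lacks the arm, and in 1RS.1BL the short arm of rye chromosome 1R stands in its place. The recombinant lines carry mixed arms: T-1 has a terminal wheat and a proximal rye segment, and 1B+5 has a terminal rye and a proximal wheat segment. Each line had 2 arrays. The series title states the purpose as placing translocation breakpoints, so the comparisons ask which transcripts depend on the wheat arm and on which segment. Signals correlated between arrays of a line with r from 0.926 to 0.980 across probe sets, and between lines with r from 0.922 to 0.973. The median absolute log2 difference between the 2 arrays was 0.34 in Pavon, 0.34 in Dt1BL and 0.37 in 1RS.1BL, against 0.18 in both T-1 and 1B+5. Dt1BL replicate 2 stood apart in 1 sign of RNA quality, with a log2 ratio of 3' to 5' sucrose synthase control signal of 5.58 against 2.63 to 3.72 on the other arrays. Its ratio for the G6PDH control, 1.48, did not stand apart and lay under the 1.59 of 1RS.1BL replicate 2. For ubiquitin its ratio was the highest, at -0.58 against -1.09 to -0.75.

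Loss of the wheat arm in Dt1BL went with large losses of signal. Relative to Pavon, 63 probe sets were lower and 6 were higher, and the median change of the lower ones was -3.78 on the log2 scale. LOC543445, on chromosome 1B, had a signal of 6197 ± 683 in Pavon and 78.8 ± 8.42 in Dt1BL (SD, n = 2), a log2 difference of -6.02 ± 0.30 (SE; limma adjusted p = 9.92e-05). Genes placed on chromosome 1A had 1 lower probe set each, LOC606369 at -4.26 ± 0.57 (adjusted p = 0.022) and LOC606345 at -1.77 ± 0.24 (adjusted p = 0.025). The other probe sets of LOC606369, at -0.44, 0.21 and 0.43, and of LOC606345, at 0.06, were not called. The largest losses were in probe sets with no gene name here, at -8.27 ± 0.69, -7.97 ± 0.59 and -7.51 ± 0.44, with Pavon signals of 12448 ± 9701, 6002 ± 1769 and 8092 ± 544. Their Dt1BL signals were 19.6 ± 20.1, 6.54 ± 2.06 and 34.4 ± 35.9, so low that background limits the order of these losses. The brightest of all those that were lower, also unnamed, dropped from 33697 ± 680 in Pavon to 176 ± 62.9. LOC778394, on chromosome 4B, was higher by both of its called probe sets, at 2.59 ± 0.34 (adjusted p = 0.0219) and 1.75 ± 0.26 (adjusted p = 0.0453). Unnamed probe sets were higher at 3.95, 3.80 and 3.64, the last with 5370 ± 1256 in Dt1BL against 410 ± 17.9 in Pavon. Without Pavon replicate 2 the lower count was 27. The higher count was 3 without Pavon replicate 1, 1 without Pavon replicate 2, 2 without Dt1BL replicate 2 or either T-1 array, and 23 without either 1RS.1BL array. It was 33 with a term for array median and 3 with array weights, and a replicate block in Pavon, Dt1BL and 1RS.1BL gave 17 higher and 117 lower.

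In 1RS.1BL, with a rye arm in place of the wheat arm, 48 probe sets were lower than in Pavon, with a median of -4.00, and 2 were higher. Of the 63 lower in Dt1BL, 46 were among them. The other 17 had a median of -1.45 here and ranged from -3.61 to 0.33, with 16 below 0. LOC543445 was at -5.78 ± 0.30 (adjusted p = 0.000168), with a signal of 96.2 ± 17.1. The unnamed probe set with the largest loss in Dt1BL was at -7.83 here and the brightest one at -7.22, with 213 ± 63.2. The 2 higher probe sets, both unnamed, were at 2.97 ± 0.27 and 2.21 ± 0.31, and the first was also higher in Dt1BL. The lower count was 28 without Pavon replicate 1, 24 without Pavon replicate 2, 236 without 1RS.1BL replicate 1 and 19 in a fit to only the 4 arrays of these lines. The higher count was 202 without 1RS.1BL replicate 1, 0 in the 4-array fit, 5 without Pavon replicate 1 or either Dt1BL array, and 1 without Pavon replicate 2 or any T-1 or 1B+5 array. It was also 1 with array weights, with no filter or with the pseudocount, the constant added before logs, at the 40th percentile, and 5 with a term for array median. A replicate block over all lines gave 1 higher, and the block in 3 lines gave 76 lower.

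Both lines without the wheat arm shared 46 lower probe sets, the wheat 1BS candidates, from 43 sequence clusters. Their median signal was 1258 in Pavon, 39.1 in Dt1BL and 42.2 in 1RS.1BL, a median 23.1-fold loss in Dt1BL and 16.7-fold in 1RS.1BL. In Dt1BL the mean of 38 candidates lay under 124.7, the highest signal on any array among the reporter control probe sets compared. A group of reporter probe sets was left out of that comparison. Independent lists of these sizes would share 0.0825 probe sets. Unchanged groups simulated against the same Pavon arrays had 0.05 called lower in Dt1BL and 0.05 in both on average, which says little about lists of these sizes. The Pavon arrays could not be split into groups of 2, so part of the excess may come from the shared controls. Across probe sets the covariance of both differences was 0.147 against 0.0677 in the simulation, with correlations of 0.66 and 0.50. The simulated arrays varied independently. Deviations of same-numbered real arrays correlated at 0.20, 0.41 and 0.22 among Pavon, Dt1BL and 1RS.1BL, which the simulated values leave out. The count of candidates was 24 without Pavon replicate 1 and 22 without Pavon replicate 2.

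No signal that came with the rye arm passed the test on this wheat array, whose response to rye transcripts was not examined. Between 1RS.1BL and Dt1BL limma called 0 probe sets higher and 0 lower, with a lowest adjusted p of 0.564. There were therefore 0 rye 1RS candidates. At an unadjusted p under 0.05, 1201 were higher and 656 lower, in sum 1857 against 1833 expected with no difference. That expectation is no firm standard here, where 1 spread per probe set was shared by lines whose arrays vary unequally. T-1 against 1B+5, with 25 higher and 19 lower called, gave 910, and Dt1BL against Pavon gave 3415. Without Dt1BL replicate 2, the array with the high 3' to 5' ratio, 14 probe sets were higher and 3 were rye candidates. Without 1RS.1BL replicate 1 there were 1 higher, 17 lower and 1 rye candidate, and without 1RS.1BL replicate 2 there was 1 lower.

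T-1, with terminal wheat and proximal rye, lacked part of the arm's signals. Against Pavon 35 probe sets were lower, 27 of them candidates, and 7 were higher. LOC543445 was at -6.60 ± 0.30 (adjusted p = 6.51e-05), and the brightest candidate was at -7.81. An unnamed probe set that is no candidate was at -5.87 ± 0.40 (adjusted p = 0.000658) in T-1, while it was at -0.41 in Dt1BL, -0.54 in 1RS.1BL and -0.22 in 1B+5. LOC606352, on chromosome 1A, was higher by 1 probe set at 1.91 ± 0.26 (adjusted p = 0.0359), and its others, at 1.71 and 1.61, were not called. The other higher probe sets were unnamed and led by one at 4.03 ± 0.36, from 186 ± 2.98 to 3303 ± 83.8. The lower count was 18 without Pavon replicate 1, 13 without Pavon replicate 2, 53 without 1RS.1BL replicate 2, 13 and 17 without T-1 replicates 1 and 2, 23 without either 1B+5 array, and 22 with the pseudocount at the 5th percentile. The higher count was 4 without Pavon replicate 1 or with that pseudocount, 0 without T-1 replicate 1 and 1 without T-1 replicate 2. Array weights gave 12 higher and 54 lower, and the replicate block in 3 lines gave 23 and 56.

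1B+5, with terminal rye and proximal wheat, lacked another part. Against Pavon 41 probe sets were lower, 32 of them candidates, and 5 were higher. LOC543445 was at -0.12 in 1B+5, with a signal of 5703 ± 7.64, close to that of Pavon. The brightest candidate was at -7.35 ± 0.31, and the largest losses after it were at -6.96 ± 0.44, -6.90 ± 0.59 and -6.78 ± 0.69 in unnamed candidates. The 5 higher probe sets, all unnamed, were at 3.51, 3.30, 2.96, 2.86 and 2.31, and the last was also higher in T-1. The lower count was 16 and 22 without Pavon replicates 1 and 2, 17 and 23 without 1B+5 replicates 1 and 2, and 27 in a fit to only these 4 arrays. The higher count was 1 without Pavon replicate 1 or either 1B+5 array, 18 without Pavon replicate 2, 9 without either 1RS.1BL array, 2 in the 4-array fit, 3 with the pseudocount at the 5th percentile, and 10 with the one at the 40th or with no filter. It was 8 with a term for array median, 11 with array weights and 23 with the replicate block in 3 lines.

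The recombinant lines differed in which candidates they lacked. Of the 46, 14 were wheat-like in T-1 and arm-lacking in 1B+5, the terminal class, with medians of -0.06 and -4.34 against Pavon. The proximal class had 9, with medians of -4.23 in T-1 and -0.14 in 1B+5, and included LOC543445. In both recombinant lines 11 were arm-lacking, each median at -4.58, and 0 were wheat-like in both. The other 12 were intermediate in at least 1 recombinant line. That label marks a difference from both references and need not mean partial wheat signal. An unnamed one was intermediate in 1B+5 at a signal of 67.3, under the highest reporter signal of 124.7, against 1898 in Pavon. Another, at 613 in 1B+5, lay below both Dt1BL at 972 and 1RS.1BL at 1103. Others lay higher, such as one at 318 in T-1 against 1590 in Pavon. The proximal class held 15 with the pseudocount at the 40th percentile and 4 at the 5th, and without Pavon replicate 2 it held 5. Without Pavon replicates 1 and 2 the terminal class held 5 and 7 and the class lacking in both 7 and 5; without replicate 1 there was 1 wheat-like in both. Without Dt1BL replicate 2 those classes held 9 and 6, and without 1RS.1BL replicate 2 the class lacking in both held 6. The terminal class held 8 with array weights, the class lacking in both held 18 with a term for array median, and the replicate block in 3 lines gave 14 proximal and 17 lacking in both. Under none of the 19 alternatives that classed candidates did a terminal candidate become proximal or the reverse. The classes lie far apart and the arrays are the same, so such a swap was unlikely in advance. Membership was less stable. The pseudocount at the 5th percentile kept 11 of the 14 terminal, 4 of the 9 proximal and 8 of the 11 candidates lacking in both in their class. Array weights kept 8, 7 and 7. Leaving out some single arrays kept still fewer of the terminal candidates and of those lacking in both.

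**Figure D1:**
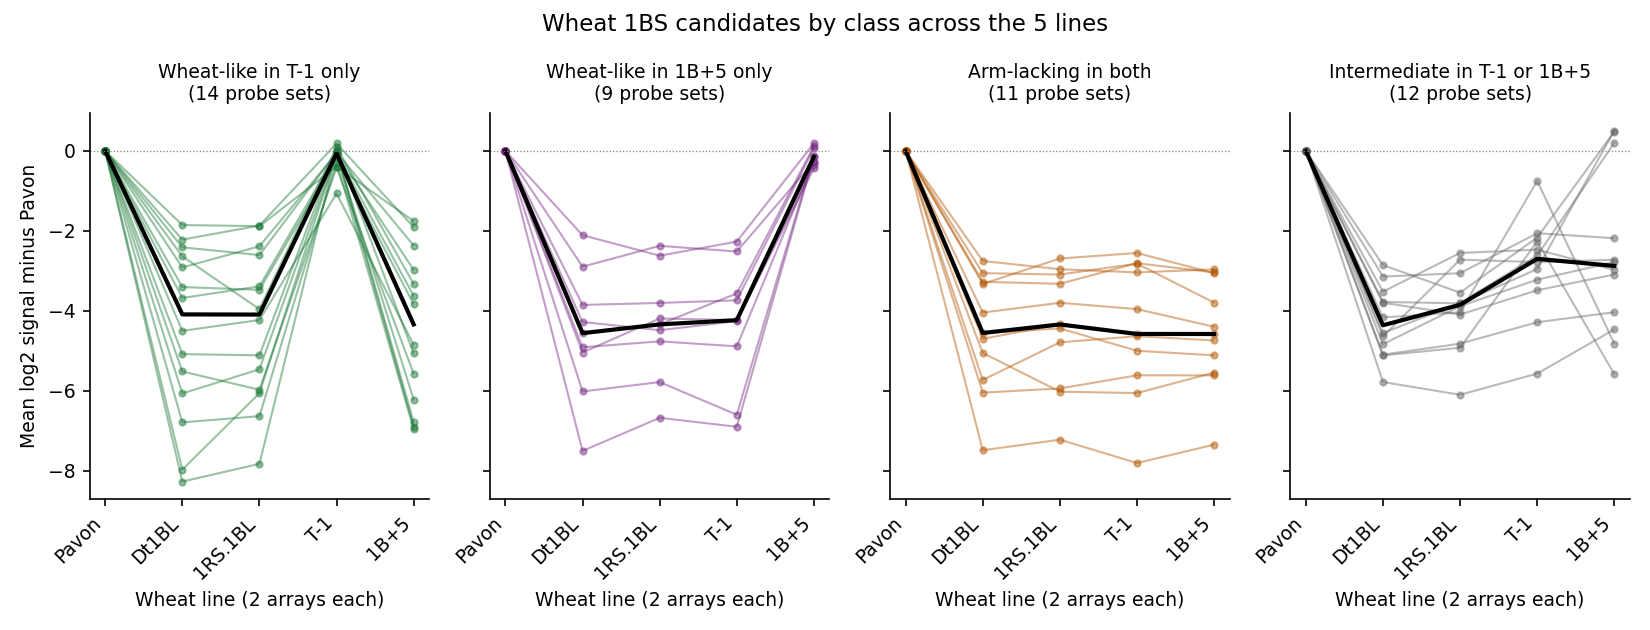
Each thin line is 1 of the 46 wheat 1BS candidates, the horizontal axis gives the wheat lines and the vertical axis the mean log2 signal of 2 arrays minus that of Pavon, with the class median in black. The 14 terminal candidates return to a median of -0.06 in T-1, the 9 proximal ones to -0.14 in 1B+5, and the 11 in the third panel stay at -4.58 in both.

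Compared directly, 25 probe sets were higher in T-1 than in 1B+5 and 19 were lower. Terminal candidates made up 12 of the 25, led by unnamed ones at 6.84 ± 0.59, 6.77 ± 0.69 and 6.67 ± 0.44. All 9 proximal candidates were among the 19, led by an unnamed one at -6.76 ± 0.44 and by LOC543445 at -6.49 ± 0.30. The classes were set with these same arrays, so this overlap is no separate test of them. Candidates of any class made up 14 of the 25 and 11 of the 19. A fit to only these 4 arrays, whose replicates lie closest, called 252 higher and 138 lower. Array weights over all 10 arrays gave 64 higher and 102 lower, so the larger direction turned, and a term for array median gave 30 lower. The higher count was 9 without either T-1 array and 12 without 1B+5 replicate 1 and 16 without replicate 2; the lower count was 8 and 9 without T-1 replicates 1 and 2, 7 and 8 without 1B+5 replicates 1 and 2, and 30 without either 1RS.1BL array.

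**Figure D2:**
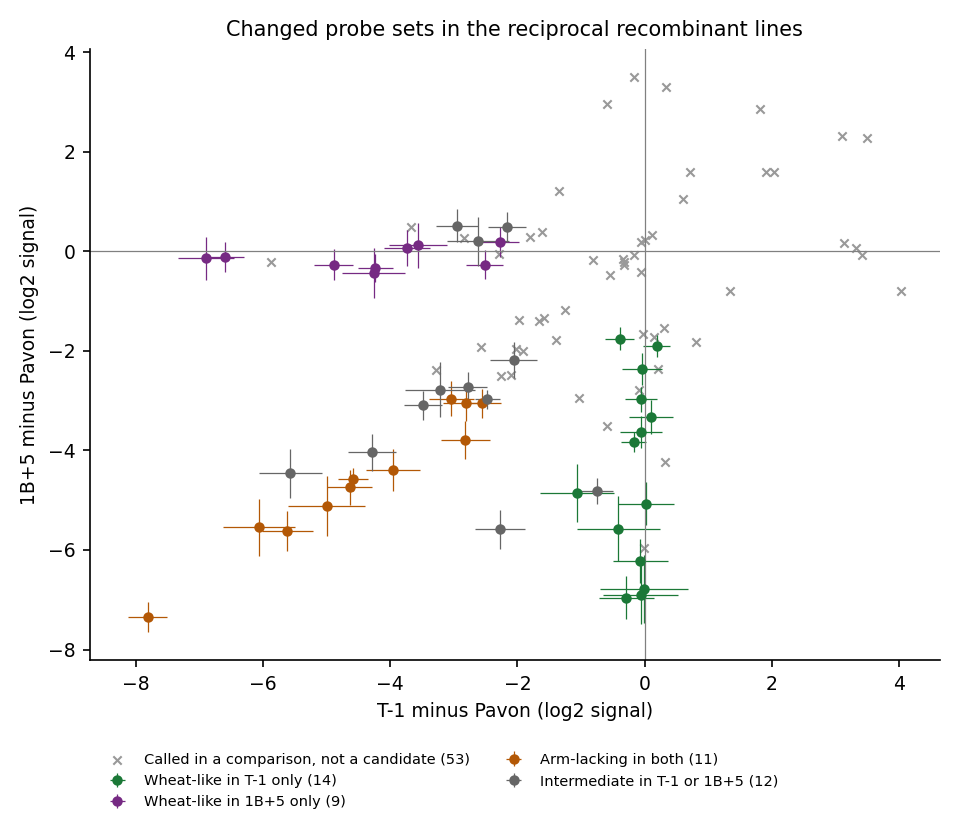
The horizontal axis is T-1 minus Pavon and the vertical axis 1B+5 minus Pavon, both in log2 signal, with SE bars on the 46 candidates and crosses for 53 other probe sets called in any comparison. Terminal candidates lie along the vertical line at 0, apart from the lowest at -1.06 in T-1, and proximal candidates along the horizontal line at 0.

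When all arrays with a segment were pooled, 26 probe sets were lower in the 6 arrays without terminal wheat than in the 4 with it. Without proximal wheat 34 were lower and 2 higher, and 0 probe sets were lower in both. Terminal candidates were 14 of the 26 and proximal ones 9 of the 34. Candidates of any class were 16 of the 26 and 12 of the 34. A segment belongs to a line, so the 2 arrays of a line are not independent replicates in this model.

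Of 15 gene groups fixed beforehand, 3 had enough probe sets for a test of the group. The 9 histone probe sets, of genes for proteins that package DNA, had a median of -0.56 in Dt1BL, where camera gave an adjusted p of 0.00194 and an adjusted p = 0.588 with an estimated correlation. Histone medians were 0.03 in 1RS.1BL, -0.22 in T-1 and -0.06 in 1B+5. The Dt1BL array with the high 3' to 5' sucrose synthase ratio is 1 of the 2 behind that histone value. The 10 tubulin and actin probe sets, of cytoskeleton genes, had medians of 0.23, 0.02, 0.07 and 0.14 in Dt1BL, 1RS.1BL, T-1 and 1B+5, with fry adjusted p-values of 0.00116, 0.0385, 0.00301 and 0.00116, while camera called none. The 9 peroxidase and glutathione transferase probe sets had medians of -0.05, 0.03, -0.03 and 0.03, with no set call, and the mean had the opposite sign in each line. After quantile normalization the peroxidase medians were 0.06, 0.03, 0.04 and 0.08, so 2 changed sign, and the histone medians in 1RS.1BL and 1B+5 changed sign too, to -0.01 and 0.03. No member of these 3 lists was called, over all probe sets or adjusted over the list alone. The 9 histone probe sets came from only 3 genes. An unnamed wheat 1BS candidate outside the list shares a sequence cluster with several of them. That candidate was called lower than Pavon in every other line. Its mean signal was 8283 in Pavon, against 299 in Dt1BL, 387 in 1RS.1BL, 325 in T-1 and 326 in 1B+5. Whether it measures a histone gene was not tested. Dehydrins and other cold or drought genes had 4 probe sets, with medians of -0.08, -1.07, -0.13 and -0.59 in the same order of lines and none called. Storage proteins, a marker of remaining endosperm, had 3 probe sets with medians of -0.47, -0.57, -0.20 and -0.42 and none called. Photosystem proteins, a leaf marker, had 3 with medians of -0.08, -0.25, 0.30 and 0.17, of which 0 were called over all probe sets and 1 in 1B+5 adjusted over the list alone.

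Named probe sets allowed a check of chromosomes in the reference table. All 3 that were lower in Dt1BL and had a chromosome lay on 1A, 1B or 1D, which hold 154 of the 998 tested, or 15.4% (Fisher's exact test, one-sided, p = 0.00361). On 1B itself lay 1 of the 3, against 31 of the 998 (exact p = 0.0904). The others lay on 1A, which Dt1BL is not described as lacking, and the remaining probe sets of their genes were not called. The smaller p thus depends on counting 1A and on very few probe sets.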

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

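The term for array median, the replicate block in 3 lines and the array weights were chosen after the data were examined. Quantile normalization and the fit without a trend moved no count by over 1.5 times. Deviations of same-numbered arrays correlated at 0.20, 0.41 and 0.22 among Pavon, Dt1BL and 1RS.1BL, and between -0.04 and 0.06 in pairs with T-1 or 1B+5. The labels do not say what the numbers mark, so samples were not taken as paired over all 5 lines, though arrays of those 3 lines deviated together. The fit with a replicate block over all lines gave 45 candidates, 43 of them shared, and among the counts moved only 1 by over 1.5 times, the higher count of 1RS.1BL against Pavon, to 1. The cause of the changes below was not tested, beyond fewer arrays in some fits. Of 46 candidates, 22 to 46 were shared with each alternative.

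The pseudocount at the 5th percentile gave 4 higher and 22 lower in T-1, 3 higher in 1B+5 and 4 proximal candidates; the 40th gave 1 higher in 1RS.1BL, 10 higher in 1B+5 and 15 proximal. Without the filter there were 1 higher in 1RS.1BL and 10 in 1B+5. Only the 4 arrays compared gave 0 higher and 19 lower in 1RS.1BL, 2 higher and 27 lower in 1B+5, and 252 higher and 138 lower for T-1 against 1B+5. Gene lists called by camera went from 1 to 0 with an estimated correlation. The term for array median gave 33 higher in Dt1BL, 5 in 1RS.1BL and 8 in 1B+5, 30 lower in T-1 than in 1B+5, and 18 candidates lacking in both. The replicate block in 3 lines gave 17 higher and 117 lower in Dt1BL, 76 lower in 1RS.1BL, 23 higher and 56 lower in T-1, 23 higher in 1B+5, 14 proximal and 17 lacking in both. Array weights, equal within each line and so a weighting of lines, gave 3 higher in Dt1BL, 1 in 1RS.1BL, 11 in 1B+5, 12 higher and 54 lower in T-1, 64 higher and 102 lower for T-1 against 1B+5, and 8 terminal.

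Leaving out 1 array, where the lone array of a line is assumed to vary like the others, gave these ranges. Higher and lower counts were 1 to 23 and 27 to 84 in Dt1BL, 1 to 202 and 24 to 236 in 1RS.1BL, 0 to 10 and 13 to 53 in T-1, and 1 to 18 and 16 to 49 in 1B+5. They were 0 to 14 and 0 to 17 for 1RS.1BL against Dt1BL, and 9 to 27 and 7 to 30 for T-1 against 1B+5. Candidates numbered 22 to 55, terminal 5 to 18, proximal 5 to 10, wheat-like in both 0 to 1 and lacking in both 5 to 16. Rye candidates numbered 0 to 3, terminal and rye-like in both 0 throughout, proximal 0 to 3 and rye-lacking in both 0 to 1. Pooled counts were 21 to 28 without terminal and 25 to 33 without proximal wheat. Of 69 tabulated differences of single probe sets, 0 changed direction under any alternative, and up to 31 lost their call under 1 alternative. Most of these differences were chosen for their size, so a change of direction was unlikely in advance. With signals of arm-lacking candidates near those of the reporter controls compared, folds are limited by background.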

Other observations

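The tests on candidates lacking in both recombinant lines, on higher probe sets, on gene order and on groupings of whole lines were chosen after the results were seen; the counts of other splits of arrays were planned. Some losses belonged to 1 recombinant line and not to the arm. One unnamed probe set had a signal of 2262 ± 422 in Pavon and 21.1 ± 15.6 in 1B+5 (SD, n = 2), a log2 difference of -5.96 ± 0.30 (limma adjusted p = 0.000109), against 0.32 in Dt1BL, 0.34 in 1RS.1BL and -0.01 in T-1. Others were at -4.22 and -2.37 in 1B+5, with differences from 0.01 to 0.32 in the other lines. These 3 probe sets were picked after their values were seen. The unnamed probe set that was higher in both Dt1BL and 1RS.1BL went the other way: its signal was 2961 ± 352 in Dt1BL and 1657 ± 148 in 1RS.1BL, against 201 ± 57.3 in Pavon, 153 ± 3.58 in T-1 and 180 ± 57.4 in 1B+5.

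The 11 candidates that were arm-lacking in both recombinant lines would be lost in both if each carried rye there. Whether the division of the arrays by median signal plays a part was not decided. Within the arrays of higher median the candidates' median difference from Pavon was -4.29, with an SD of 1.35 between members. All arrays of both recombinant lines lie on that side, and members were chosen as low in those lines. A loss there was therefore built in, so the value is no separate test. A difference of Pavon from all other lines outside the arm stays open: 100% of the 16 probe sets called the same way in all 4 lines were lower, but all 16 are candidates, chosen as lower. A position where both lines carry rye stays open too, because 0 of the 11 have a position in the reference table. A stretch of wheat missing from both lines is therefore only a hypothesis.

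The 7 probe sets higher in T-1 and the 5 higher in 1B+5 might come from array conditions shared by T-1 and 1B+5, or from their rye segments. The median difference between the recombinant lines was 2.96 for the T-1 set and 2.97 for the 1B+5 set. Members were chosen as high in 1 of these lines, which favours such a difference. Shared array conditions are argued against only for members that stayed near Pavon in the other recombinant line. They stay open for the probe set higher in both and for LOC606352, at 1.60 in 1B+5. The same holds for an unnamed one of the T-1 set, at 2.27 in 1B+5. It also holds for an unnamed one of the 1B+5 set, at 1.81 in T-1. The rye segment is argued against as the whole source, since in 1RS.1BL, with the complete rye arm, the medians were 0.15 and 0.11 from Pavon, with SDs of 0.39 and 0.56 between members. Differences in the background of each recombinant line, which their crosses could have brought, stay open and were not tested.

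If the genes lost in Dt1BL lay at the start of chromosome 1B, the difference should rise along it. Over 24 named genes on 1B, Spearman's rho between order and the Dt1BL difference was 0.25 and Pearson's r was 0.36 (permutation p for rho = 0.241, adjusted 0.79 over 84 relations), and rho without LOC543445 was 0.15, so the order was not decided; genes are not independent replicates. The value that would have argued against the order was first set as a permutation p of 0.05 or more and was changed to a rho of 0 or below after this p was seen, because a p that misses the threshold excludes nothing. The rho for 1B ranked 4 among 21 chromosomes, and the largest on 1B was 0.58 in T-1 (p = 0.00327, adjusted 0.275). LOC543445, in the proximal class, is number 2 of the 24.

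Other splits of the 10 arrays into 4 and 6 were counted over 100 of 210 possible splits, including the real one and the one that follows array median. For terminal wheat 4 of the 100 gave as many lower probe sets as the real 26, and for proximal wheat 5 gave as many as the real 34. A segment belongs to a line, and 5 lines make only 10 groupings of 2 and 3, too few for a share under 0.05. Counting the real one, 4 of these groupings reached the real 26 for terminal wheat. For proximal wheat 3 reached the real 34. The highest other grouping of lines, T-1 and 1B+5 against the rest, gave 209. The highest other split of arrays, at 1352 lower and 3835 higher, set Pavon 1, Dt1BL 1, Dt1BL 2 and 1RS.1BL 1 against the rest. It points to a structure of the arrays: those 4 had medians from 88.2 to 92.1 and a dap spike signal from 5225 to 9332, against 2125 to 4458 on the others. With a term for that division, 29 probe sets were lower without terminal wheat and 34 without proximal wheat.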
